A study of Mus musculus with 26 samples.

How the data were processed

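The series holds 26 samples of mouse femoral osteoblasts grown in culture. RNA was sequenced in 18 of them, and the other 8 are H2AK119ub1 CUT&Tag libraries, a profile of a histone mark that PRC1 lays down, which are not analysed here. The authors deposited raw read counts per gene symbol, and no normalization had been applied, since the deposited columns hold whole numbers that sum to 46.27 to 77.7 in units of 1e6. FastQC, Trim Galore and HISAT2 and the mm39 genome build are named in the submitters' processing notes, and their versions are not given in the sources used here. The program that counted reads, the gene annotation and whether strand was used are not given in the sources used here either, so genes that overlap or lie antisense to one another, and near-identical paralogs, could not be told apart by their counts. Of the 26264 symbols, 24964 matched a table of gene names and 20832 had at least 1 count. No mitochondrially encoded gene was among the symbols, so a list of these genes could not be tested and the mitochondrial share of the counts was not used here. Neighbours of Kdm2b were looked up in a gene table of the GRCm38 assembly, used for gene order alone.

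Samples were placed in groups by the submitters' titles, 3 libraries in each of the 6 RNA groups: YOUNG and OLD (mice of 3 and 18 months), CON-YOUNG, CKO-YOUNG, CKO-OLD and CON-OLD-iBP. The comparisons, tests, gene lists, rule for named genes and main alternatives were fixed before the data were examined. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 16566, scaled by TMM, and tested with edgeR's quasi-likelihood F test (robust fit, 1 coefficient per group over all 18 libraries, 12 residual degrees of freedom) with Benjamini-Hochberg adjustment over the genes of a contrast and a threshold of 0.05. Adjusted p-values of single genes in the text are from this test, two-sided, unless another tool is named. Values per library are CPM (counts scaled to a library size of 1e6) computed from the deposited counts with TMM library sizes, and mean ± SD is over the libraries of a group. A fold against a group at 0 was computed against a floor of 3 counts over the group and written as a lower bound; floors cover counting error only. The depth gives 1 count a value of 0.0129 to 0.0216 CPM. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.

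Fixed lists of bone, Wnt, Polycomb, signalling, stress, metabolic and cell type marker genes, 43 with at least 3 tested members, were tested with limma camera with a preset correlation between genes of 0.01, adjusted over the lists of a contrast. Alternatives were camera with an estimated correlation and fry, which asks whether the members of a list move one way on balance and does not compare them with other genes. Single members were also adjusted over the list alone. With an estimated correlation, camera kept the developmental transcription factors in CKO-OLD against OLD and in CKO over both ages, and the osteoblast genes in OLD against YOUNG, and no other list of the 10 comparisons. The rule for named genes takes Kdm2b, Axin2, Lef1, Bglap and Cdkn2a in each comparison; the 8 largest increases and 8 largest decreases (3 in the secondary comparisons) among genes past the threshold, with a mean of at least 5 CPM in the higher group and groups that do not overlap; and the 3 members of smallest adjusted p from the 6 lists (3 in the secondary comparisons) of smallest camera p that have at least 2 such genes. Predicted symbols, Xist and Y-linked genes were left out. Other members of lists given as examples, such as Wnt6, Mki67 or Acp5, are among those of smallest p in their list or were chosen after their values were seen, as were Bcor, Isg15, Irf7, H19, Klra4 and Igf2 outside the rule, and Tcfl5 in CKO-YOUNG.

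Libraries were compared by Malat1 share, Xist, Y-linked genes and marker genes, and were placed in 3 sets. Set 3 held the libraries above 0.05% Malat1. Those below it were parted by group label, YOUNG and OLD in set 1 and CON-YOUNG and CKO-YOUNG in set 2. Fits with a term for library set, with 1 coefficient per group and set (10 coefficients, 8 residual degrees of freedom) and without set 1 were added after the data were seen, as were the contrast of CKO over both ages and the test of the 21 CKO-YOUNG genes in other contrasts. The biological coefficient of variation was 51.9% with group coefficients, 39.7% with a set term and 33.9% with coefficients within sets. OLD 1 and OLD 3 had the highest correlation of any pair (Spearman 0.995). Their median squared difference was 6.23 times that of counting noise, against 16 to 113 in the other pairs of one group and set. They were kept as 2 libraries, though this does not show that they are separate samples. Replicate numbers come from the titles. The deviations of same-numbered libraries from their group means correlated at 0.193, 0.237 and 0.305 in CKO-YOUNG and CON-YOUNG and at 0.146, 0.245 and 0.31 in CON-YOUNG and YOUNG. Replicate 3 of each of these groups is in set 3. CKO-YOUNG 1 correlated better with CON-YOUNG 2 (0.236) than with CON-YOUNG 1, and CON-YOUNG 1 better with YOUNG 2 (0.272) than with YOUNG 1. Pairing by number beyond library set is therefore not shown. In the other comparisons at least 1 pair lay under 0.1.

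Alternatives tried were median-ratio size factors, library totals, DESeq2, limma-voom with quality weights, no filter, a filter of 5 CPM in 3 libraries, removal of the 20 genes of highest counts, the groups of a comparison alone, the replicate block, a fold threshold of log2 1 and each library left out in turn. The tests were checked on simulated counts in 3 simulations of 200 changed genes for each of 4 comparisons (16185 genes). In the simulation of CKO-YOUNG against CON-YOUNG edgeR called 12.9%, 71.1% and 87.9% of genes changed by log2 1, 2 and 3, of CKO-OLD against OLD 11.9%, 60.7% and 83.3%, of OLD against YOUNG 17.4%, 66.2% and 79.3%, and of CON-OLD-iBP against OLD 14.4%, 59.7% and 82.3%. Over the 3 simulations of a comparison, 47861 to 47938 tests were of unchanged genes. DESeq2 called 120 to 163 of these, edgeR 6 to 9 and limma-voom 5 to 12, so DESeq2 made more false calls in these simulations. The spread was simulated from edgeR's own estimates, without differences in quality between libraries. The simulations therefore do not check the limma-voom counts of the real data, most of them far above those of edgeR. Camera and fry each found 12 of 12 raised lists and 0 of 12 unchanged ones. The simulated genes were drawn independently and without library sets, so this does not check lists whose members move together.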

Results

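Gene expression was measured by RNA sequencing in cultured mouse femoral osteoblasts, the cells that lay down bone matrix. The 18 RNA libraries formed 6 groups of 3. YOUNG and OLD came from C57BL/6J mice of 3 and 18 months. CKO-YOUNG and CKO-OLD carried a conditional deletion of the CxxC domain of Kdm2b, the DNA-binding part of a subunit of the Polycomb complex PRC1.1, driven by Ocn-cre with an Ai14 reporter. CON-YOUNG was the control with the driver and reporter alone. CON-OLD-iBP was an old control group given iBP, a code name that the labels do not expand. Total counts per library, in units of 1e6, ran from 56.79 to 77.7 in YOUNG, 53.85 to 67.72 in OLD, 54.86 to 64.79 in CON-YOUNG, 60.56 to 64.65 in CKO-YOUNG, 46.27 to 53.25 in CKO-OLD and 46.49 to 55.82 in CON-OLD-iBP. No label says that the replicates came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical. The groups analysed here include no untreated old control of the knockout line, so OLD, of another mouse line, served as the untreated old reference.

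The libraries fell into sets that crossed the groups. The nuclear RNA Malat1 took 0.0296% to 0.0435% of the counts in 8 libraries and 0.0957% to 0.223% in the other 10. The low libraries were YOUNG 1 and 2 and OLD 1 and 3 (set 1) and CON-YOUNG 1 and 2 and CKO-YOUNG 1 and 2 (set 2). Set 3 held YOUNG 3, OLD 2, CON-YOUNG 3, CKO-YOUNG 3, and all of CKO-OLD and CON-OLD-iBP. Set 1 expressed Xist, the transcript of the inactive X chromosome of females, at 391 to 481 CPM (counts scaled to a library size of 1e6), with 0 CPM of the Y-linked gene Ddx3y. The libraries of sets 2 and 3 had 21.3 to 91.8 CPM of Ddx3y, and only CKO-YOUNG 3 among them had Xist as well, at 372 CPM. Transcripts of 26 macrophage and monocyte marker genes made up 1.11% to 1.72% of the counts in set 1, 0.016% to 0.0223% in set 2 and 0.0535% to 0.677% in set 3. The first principal component held 34.8% of the variance, and library set accounted for 86.8% of it against 75.7% for group. Libraries of one group in different sets correlated less (median Spearman correlation across genes 0.9385, 8 pairs) than libraries of different groups in one set (0.959, 47 pairs). CKO-YOUNG 3 stood apart from the rest of set 3: it was alone in its cluster when the libraries were grouped into 4. Its first component was 56, against -82.3 to -20.5 in the others of set 3. Its correlations were 0.943 to 0.95 with set 2, 0.941 to 0.951 with CKO-OLD and 0.894 to 0.927 with CON-OLD-iBP. YOUNG 3 correlated at 0.976, 0.97 and 0.958 with CON-OLD-iBP 1, 2 and 3, against 0.929 and 0.934 with YOUNG 1 and 2. Counts within set 3 or with a set term that involve CKO-YOUNG rest on placing CKO-YOUNG 3 in set 3 by Malat1. Set 3 was parted from the others by Malat1, as seen in the data. Sets 1 and 2 were parted by group label, YOUNG and OLD against CON-YOUNG and CKO-YOUNG. The share of the first component given to library set therefore holds part of the group label. The sets are not groups of the study. Counts within sets and with a term for library set stand beside pooled ones. Where a group has 1 library in a set, other groups supply the spread, so such counts describe single libraries.

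**Figure D1:**
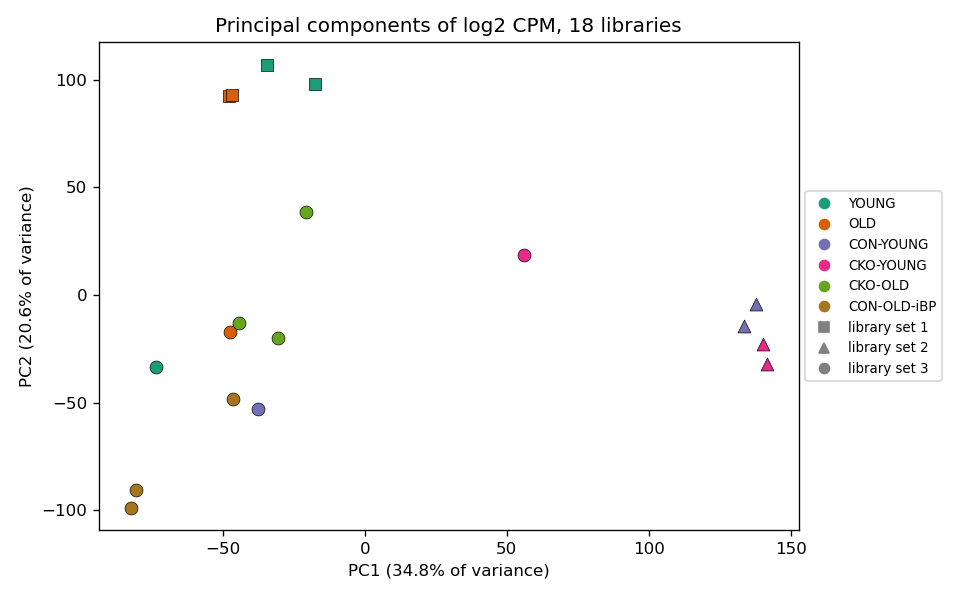
Principal components 1 (34.8% of the variance) and 2 (20.6%) of log2 CPM for the 18 libraries, with color for the group and marker shape for the library set. The libraries of sets 1 and 2 of YOUNG, OLD, CON-YOUNG and CKO-YOUNG lie apart from the set 3 library of the same group.

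Kdm2b, the targeted gene, was read in every library. It stood at 51.5, 58.2 and 27.6 CPM in CKO-YOUNG 1, 2 and 3, against 48.8, 52.9 and 19.9 CPM in CON-YOUNG 1, 2 and 3, and did not differ (log2 fold change within set 2 0.11, edgeR adjusted p = 1). CKO-OLD held 23.4, 57.2 and 28.4 CPM, OLD 34.3, 19.3 and 31.1 CPM, YOUNG 37.2, 37.5 and 22.6 CPM, and CON-OLD-iBP 19.3, 24 and 16.2 CPM. Within set 3 Kdm2b was lower in CON-OLD-iBP than in CKO-OLD by -0.87 (adjusted p = 0.0475). Counts summed over the whole gene do not check the deletion of one domain, so these values neither bear out nor contradict the knockout label.

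Osteoblasts of CKO-YOUNG and CON-YOUNG were compared to ask which genes change when the Kdm2b domain is lost at a young age. There were 21 genes higher in CKO-YOUNG and 0 lower at an edgeR adjusted p under 0.05, each by more than 2-fold. Tmem132e, a membrane protein gene, stood at 22 ± 0.526 CPM (SD, n = 3) in CKO-YOUNG and at 0 in all 3 CON-YOUNG libraries. This is at least 1240-fold higher against a floor of 3 counts over the group (adjusted p = 0.0283). Tcfl5, a basic helix-loop-helix transcription factor, rose from 5.45 ± 3.12 to 49.6 ± 2.39 CPM (log2 fold change 3.18, adjusted p = 0.00942). Mafa, a transcription factor best known from pancreatic beta cells, rose from 0.767 ± 0.152 to 11.7 ± 4.56 CPM (3.92, adjusted p = 0.00517). The growth factor midkine, Mdk, rose from 0.776 ± 0.152 to 15 ± 5.09 CPM (4.27, adjusted p = 0.0128). The natriuretic peptide receptor Npr1 rose from 0.486 ± 0.0744 to 21.8 ± 6.54 CPM (5.48, adjusted p = 0.0343). Adgrb1, an adhesion G protein-coupled receptor, rose from 0.165 ± 0.0451 to 19.2 ± 6.55 CPM, and Ina, a neuronal intermediate filament, from 0.21 ± 0.0722 to 6.57 ± 3.19 CPM. Cntfr, the receptor of ciliary neurotrophic factor, rose from 1.6 ± 0.824 to 16.5 ± 3.35 CPM, and the calcium channel gene Cacna1h from 1.7 ± 0.783 to 34 ± 36.1 CPM. Cacna1h was at 17.2, 9.24 and 75.4 CPM in CKO-YOUNG 1, 2 and 3, and without CKO-YOUNG 3 its log2 fold change was 2.96 and not called (adjusted p = 0.116). Axin2 and Lef1, targets of Wnt signalling through beta-catenin, did not pass. Axin2 stood at 5.5 ± 4.24 against 2.44 ± 1.68 CPM (adjusted p = 0.973) and Lef1 at 6.62 ± 4.45 against 1.88 ± 0.743 CPM (adjusted p = 0.97). Bglap, which encodes the bone matrix protein osteocalcin, was at 0.153 ± 0.153 against 3.35 ± 5.66 CPM (adjusted p = 0.55). The cell cycle inhibitor gene Cdkn2a was at 31.5 ± 45.6 against 54.3 ± 80.2 CPM (adjusted p = 1).

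Of the 57 tested transcription factor genes of development that Polycomb complexes are known to bind, 37 were positive and 19 negative, with a median log2 fold change of 0.40. None passed over all genes by edgeR, and 3 were higher adjusted over the list alone. The list was higher by limma camera (adjusted p = 0.000388; adjusted p = 0.232 with an estimated correlation). Lhx2, a limb and forebrain factor, was at 24 ± 7.17 against 2.27 ± 1.75 CPM. Foxl2, an ovarian factor, was at 3.88 ± 1.42 against 0.0924 ± 0.0802 CPM (adjusted p = 0.255). Wnt ligands and R-spondins passed as well, with 11 of 19 positive and 2 higher adjusted over the list alone (camera adjusted p = 0.00688). Their adjusted p = 0.342 with an estimated correlation. Wnt6 stood at 5.66 ± 1.84 against 0.0674 ± 0.117 CPM (adjusted p = 0.141). Of 40 cell cycle genes, 35 were negative with a median of -0.22 and none passed (camera adjusted p = 0.00415, and adjusted p = 0.882 with an estimated correlation). Their mean log2 CPM was 6.02 and 6.1 in CKO-YOUNG 1 and 2, against 6.09 and 6.1 in CON-YOUNG 1 and 2. It was 4.04 in CKO-YOUNG 3 against 5.14 in CON-YOUNG 3, so the direction rests mainly on CKO-YOUNG 3. Hox genes, of which 21 of 35 were positive, had a camera adjusted p of 0.043, glycolysis and hypoxia genes 0.0296, and pericyte and smooth muscle markers 0.0296. With an estimated correlation the adjusted p of these lists was 0.845, 0.845 and 0.882. Within set 2, with 2 libraries a group, 76 genes passed (62 higher, 14 lower), 15 of the 21 among them. With a term for library set 93 passed (78 higher, 15 lower). CKO-YOUNG 3 against CON-YOUNG 3, 1 library a side, gave 1113 (561 higher, 552 lower), with Bglap lower at 0.306 against 9.89 CPM (adjusted p = 0.0117). Same-numbered libraries correlated in their deviations, which may reflect only that both replicates 3 are in set 3. With the replicate as a block 0 genes passed by edgeR. That fit held the libraries of these 2 groups alone, with fewer residual degrees of freedom than the 4 left without a block. The 0 therefore does not show that pairing removes the difference. Without a block, the edgeR fit over all 18 libraries gave 907 genes at an unadjusted p under 0.05. DESeq2 called 230 and limma-voom 499, also without a block. Under the block 8 lists passed camera in place of 6. The count of 21 was 3, 2, 7, 8 and 10 without CON-YOUNG 1, CON-YOUNG 2, CKO-YOUNG 1, CKO-YOUNG 2 or CKO-YOUNG 3.

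**Figure D2:**
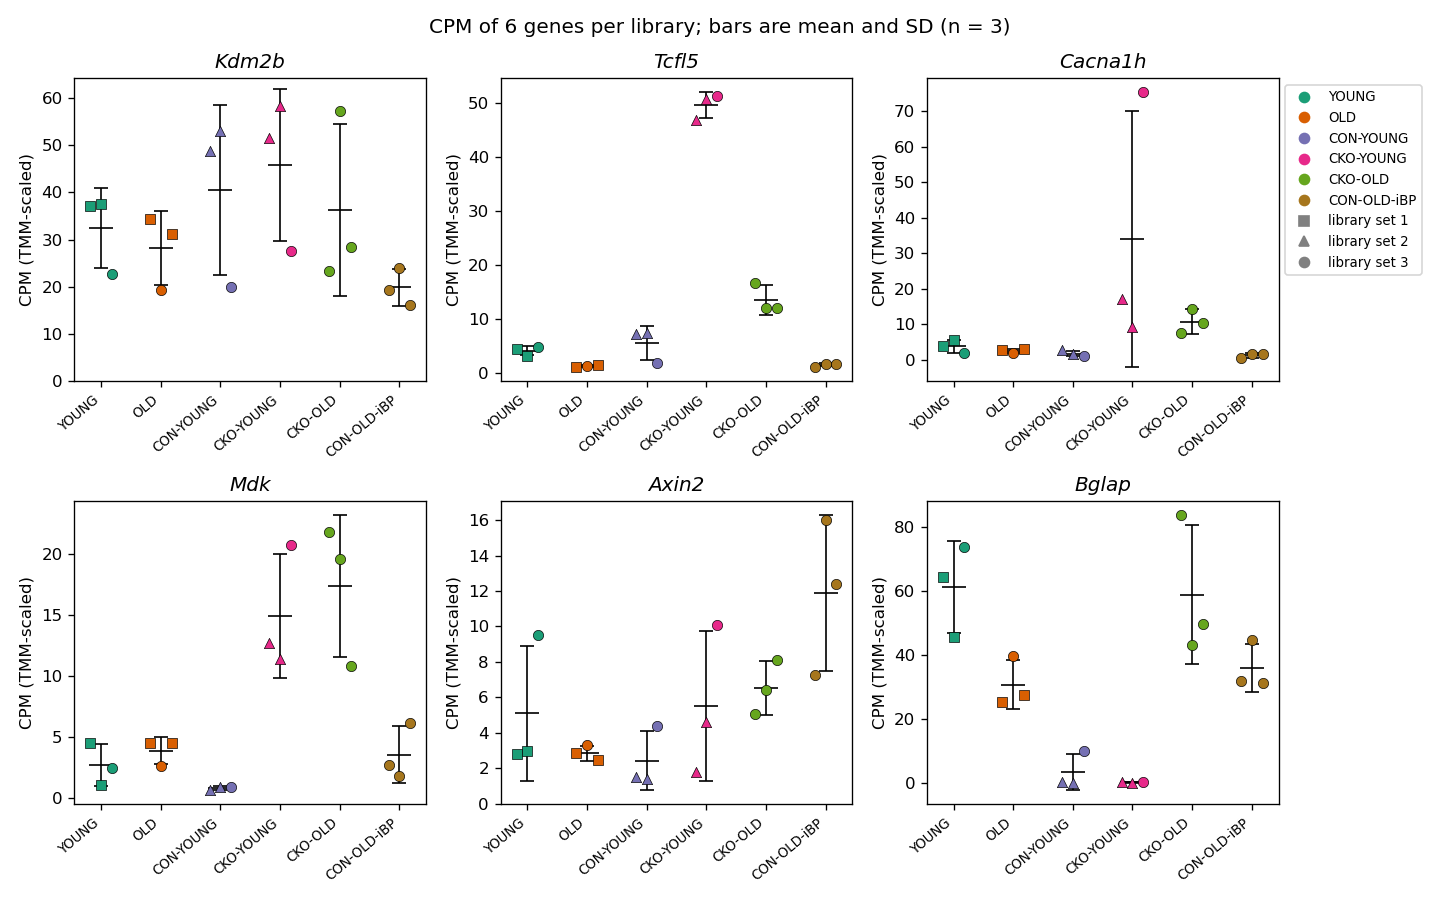
CPM of Kdm2b, Tcfl5, Cacna1h, Mdk, Axin2 and Bglap in each of the 18 libraries by group; points are libraries, marker shape gives the library set, and bars give the mean and SD of the 3 libraries of a group. Tcfl5 lies at 49.6 ± 2.39 CPM in CKO-YOUNG and 13.5 ± 2.72 CPM in CKO-OLD, above every library of the other groups, while Kdm2b in the CKO libraries overlaps with CON-YOUNG and OLD.

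In old cells, CKO-OLD against OLD, Tcfl5 was the single gene past the threshold. It rose from 1.16 ± 0.202 to 13.5 ± 2.72 CPM (n = 3; log2 fold change 3.53, edgeR adjusted p = 0.00706), and within set 3 by 3.55 (adjusted p = 0.0213). Axin2 stood at 6.51 ± 1.53 against 2.86 ± 0.422 CPM (adjusted p = 0.644) and Lef1 at 1.31 ± 0.628 against 0.163 ± 0.157 CPM (adjusted p = 0.494). Bglap stood at 58.8 ± 21.7 against 30.7 ± 7.75 CPM (adjusted p = 0.88) and Cdkn2a at 106 ± 34 against 159 ± 18.5 CPM (adjusted p = 0.933). The developmental transcription factor list was higher in CKO-OLD, with 50 of 57 members positive, a median of 1.06 and 2 higher adjusted over the list alone. Its camera adjusted p was 2.48e-11, and adjusted p = 0.00258 with an estimated correlation. Nkx6-1, a neural tube and islet factor, stood at 2.28 ± 0.983 against 0.0579 ± 0.1 CPM and Foxl2 at 3.05 ± 1.01 against 0.0862 ± 0.0498 CPM. In CON-OLD-iBP 1, 2 and 3, without the knockout, Nkx6-1 was at 4.02, 1.19 and 2.78 CPM and Foxl2 at 0.364, 0.349 and 0 CPM. The Nkx6-1 level therefore does not mark the knockout. Within set 3, where OLD 2 is the only OLD library, 41 of the 57 were positive (camera adjusted p = 3.74e-06; adjusted p = 0.0473 with an estimated correlation).

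Wnt genes lay higher in CKO-OLD as lists. Of 19 ligands and R-spondins, 18 were positive with a median of 1.23 and 2 were higher adjusted over the list alone (camera adjusted p = 3.04e-05; adjusted p = 0.0857 with an estimated correlation). Wnt10b, a ligand that promotes bone formation, was at 24.7 ± 8.3 against 6.87 ± 2.35 CPM and Wnt6 at 2.52 ± 1.04 against 0.0757 ± 0.0425 CPM. Wnt receptors (29 of 34 positive), Wnt antagonists (12 of 14) and Wnt target genes (19 of 27) had camera adjusted p of 0.000306, 0.0128 and 0.0482. With an estimated correlation their adjusted p was 0.385, 0.338 and 0.338. The secreted antagonists Frzb (22.7 ± 6.98 against 3.84 ± 1.19 CPM) and Wif1 (62.6 ± 29.3 against 13.9 ± 3.29 CPM) were higher adjusted over the list alone. Osteoblast matrix and differentiation genes had 26 of 34 positive with a median of 0.53 and no member past the threshold (camera adjusted p = 0.000602; adjusted p = 0.251 with an estimated correlation). Hox genes had 28 of 35 positive, as many as in CON-OLD-iBP against OLD (camera adjusted p = 6.28e-05, and adjusted p = 0.164 with an estimated correlation). PRC1 subunit genes had 20 of 28 positive (camera adjusted p = 0.0127; adjusted p = 0.365 with an estimated correlation). The growth factor Igf2 stood at 96 ± 39.4 against 1.75 ± 0.521 CPM. Its list, Hedgehog, FGF and IGF signalling, had 4 members higher and 1 lower adjusted over the list alone (camera adjusted p = 6.28e-05; adjusted p = 0.208 with an estimated correlation).

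Markers of other cell types moved in the same comparison. All 26 macrophage markers were negative (median -1.77, camera adjusted p = 1.81e-09; adjusted p = 0.385 with an estimated correlation). Macrophage transcripts took 1.24%, 0.161% and 1.23% of OLD 1, 2 and 3 and 0.158% to 0.677% of CKO-OLD. Of 15 osteoclast markers 14 were negative (camera adjusted p = 1.37e-08; adjusted p = 0.164 with an estimated correlation), and of 18 chondrocyte markers 15 were positive (0.00165; adjusted p = 0.566 with an estimated correlation). Against OLD 2 alone, within set 3, 25 of the 26 macrophage markers were instead positive (median 1.12, camera adjusted p = 3.74e-06; adjusted p = 0.665 with an estimated correlation). In that set Wnt ligands (16 of 19), Wnt targets (18 of 27) and osteoblast genes (28 of 34) were again mostly positive, with camera adjusted p of 0.000144, 0.00239 and 8.88e-05. The adjusted p was 0.407, 0.407 and 0.562 with an estimated correlation. Within set 3, 9 genes passed (4 higher, 5 lower), and with a term for library set 4 (3 higher, 1 lower). Without OLD 1 or OLD 3, or without set 1, 0 genes passed by edgeR, and without OLD 2 there were 48. At an unadjusted p under 0.05 there were 1352 genes, with 181 called by DESeq2 and 6820 by limma-voom, which gave OLD 1 and 3 quality weights of 4.69 and 4.94.

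The knockout contrast was also averaged over both ages, a comparison added after the data were seen, with 6 libraries a side. It called 88 genes, 86 higher and 2 lower. Tmem132e was at 15.5 ± 7.78 CPM in the 6 CKO libraries and at 0 in the 6 others, at least 1870-fold higher (adjusted p = 0.00243). Tcfl5 rose from 3.31 ± 3.07 to 31.5 ± 19.9 CPM (n = 6; log2 fold change 3.36, adjusted p = 0.000126) and Mdk from 2.32 ± 1.83 to 16.2 ± 5.07 CPM (3.22, adjusted p = 0.002). Npr1 rose from 0.4 ± 0.108 to 13.4 ± 10.2 CPM and Adgrb1 from 0.153 ± 0.0866 to 11.1 ± 9.8 CPM. The glutamate receptor gene Grid1 rose from 0.637 ± 0.875 to 19 ± 7.35 CPM, Trank1 from 0.753 ± 0.505 to 8.66 ± 6.14 CPM and Igf2 from 4.38 ± 6.11 to 310 ± 522 CPM (6.00, adjusted p = 0.0302). Igf2 was at 1370 CPM in CKO-YOUNG 3 and at 50.7 to 123 CPM in the other 5 CKO libraries, and without CKO-YOUNG 3 its log2 fold change was 4.79 and not called (adjusted p = 0.0601). Of the developmental transcription factors, Foxl2 (0.0893 ± 0.0598 to 3.47 ± 1.19 CPM) and Lhx2 (1.55 ± 1.39 to 14.7 ± 11.1 CPM) rose. In that list 8 were higher adjusted over the list alone and 45 of 57 were positive (camera adjusted p = 6.74e-12; adjusted p = 0.00361 with an estimated correlation). Wnt6 rose from 0.0715 ± 0.0787 to 4.09 ± 2.18 CPM (5.70, adjusted p = 0.0138). Of the 19 Wnt ligands, 4 were higher adjusted over the list alone (camera adjusted p = 5.5e-06; adjusted p = 0.0568 with an estimated correlation). The receptor gene Fzd10, the antagonist Frzb and the PRC1.1 subunit Bcor (49.2 ± 27.5 to 137 ± 65.3 CPM, adjusted p = 0.0357) were the single called members of their lists. Wnt receptors, Wnt antagonists and PRC1 subunits had camera adjusted p of 0.000491, 0.0118 and 0.00994, and of 0.519, 0.429 and 0.429 with an estimated correlation. Cell cycle genes were lower (37 of 40 negative, camera adjusted p = 7.75e-05, and adjusted p = 0.714 with an estimated correlation), with none past the threshold. Their mean log2 CPM was 4.75, 5.02 and 4.82 in CKO-OLD 1, 2 and 3, against 5.36, 4.9 and 5.36 in OLD 1, 2 and 3. Only OLD 2 of these OLD libraries is in set 3. In the young groups the direction rests mainly on CKO-YOUNG 3 (4.04), so the lower list is not told apart from library set and that library. Macrophage markers (24 of 26 negative), osteoclast markers (13 of 15), marrow stroma genes (10 of 14) and ribosomal protein genes (42 of 45) were lower as lists, with camera adjusted p of 0.00305, 5.15e-05, 0.018 and 0.00106. Hox genes (24 of 35 positive) and Hedgehog, FGF and IGF signalling (19 of 30) were higher (camera adjusted p = 6.39e-05 and 0.00994). These 6 lists had adjusted p of 0.714, 0.429, 0.684, 0.714, 0.195 and 0.445 with an estimated correlation. The difference of the knockout contrast between old and young was tested directly. It called 0 genes by edgeR, with 796 at an unadjusted p under 0.05, 48 by DESeq2 and 2742 by limma-voom. The count of 88 became 24, 29, 42, 50, 46, 52 and 55 without OLD 1, OLD 3, CKO-OLD 2, CKO-OLD 3, CON-YOUNG 1, CON-YOUNG 2 or CKO-YOUNG 2, and 1 without the 4 libraries of set 1. It was 50 with the replicate as a block and 129 with a term for library set. Tcfl5, Tmem132e, Adgrb1, Npr1 and Mdk were called in each of 21 alternatives other than those on library set, Lhx2 in 9 of 21, Igf2 in 10 of 21 and Foxl2 in 16 of 20. Without set 1 none of these first 5 passed. The log2 fold changes of Tcfl5, Adgrb1, Npr1 and Mdk were then 3.37, 5.22, 4.8 and 3.51, against 3.36, 5.62, 4.72 and 3.22 with it, so the lost calls do not show that set 1 carried them.

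OLD against YOUNG asked what age changes in cultured wild-type osteoblasts. Genes of osteoblast matrix and differentiation lay lower in OLD, with 30 of 34 members negative, a median log2 fold change of -0.85 and 3 lower adjusted over the list alone. The camera adjusted p was 5.29e-12, and adjusted p = 0.0263 with an estimated correlation. Smpd3, a phosphodiesterase needed for bone mineralisation, stood at 4.83 ± 2.07 CPM in OLD against 26.3 ± 1.22 CPM in YOUNG (n = 3). The collagen gene Col1a1 stood at 8780 ± 2720 against 16100 ± 2000 CPM and Bglap at 30.7 ± 7.75 against 61.1 ± 14.4 CPM. None of these passed over all genes. Within set 1, 29 of the 34 were negative (camera adjusted p = 1.6e-07; adjusted p = 0.32 with an estimated correlation). Wnt target genes (23 of 27 negative, 3 lower adjusted over the list alone) and Wnt ligands (15 of 19 negative) were also lower as lists (camera adjusted p = 0.00112 and 0.0154). With an estimated correlation their adjusted p was 0.145 and 0.292, and within set 1 the targets had a camera adjusted p of 0.523. Axin2 stood at 2.86 ± 0.422 against 5.1 ± 3.81 CPM, Lef1 at 0.163 ± 0.157 against 2.5 ± 2.35 CPM and Cdkn2a at 159 ± 18.5 against 157 ± 57.3 CPM. Osteoclast markers lay higher, 12 of 15 positive with 6 higher adjusted over the list alone (camera adjusted p = 3.08e-10; adjusted p = 0.145 with an estimated correlation). Acp5, the tartrate-resistant acid phosphatase, was at 596, 25.8 and 632 CPM in OLD 1, 2 and 3 and at 6.49 to 14 CPM in YOUNG. Within set 1, 14 of the 15 were positive and 9 were higher adjusted over the list alone (camera adjusted p = 1.15e-13; adjusted p = 0.0751 with an estimated correlation). Macrophage markers, of which 23 of 26 were negative, had a camera adjusted p of 0.0355 (adjusted p = 0.949 with an estimated correlation). Nuclear oxidative phosphorylation genes (36 of 40 positive, median 0.15) and ribosomal protein genes (43 of 45 positive, median 0.14) had camera adjusted p of 0.000297 and 0.00214. Their adjusted p was 0.739 and 0.882 with an estimated correlation. No gene passed by edgeR, against 554 at an unadjusted p under 0.05, 41 by DESeq2 and 1125 by limma-voom, and leaving out YOUNG 3 gave 2. Within set 1, with 2 libraries a group, 63 genes passed (53 higher, 10 lower). OLD 1 and 3, the OLD side of set 1, were the most alike pair of the series, so their spread may not measure that between samples. Among the 63 the matrix protease Mmp3 rose from 1.03 ± 0.737 to 155 ± 1.08 CPM (n = 2), while in set 3 it was at 910 CPM in YOUNG 3 and 71.8 CPM in OLD 2. Tnfaip3, an inhibitor of NF-kappaB, fell from 153 ± 6.01 to 24.8 ± 0.561 CPM, and in set 3 it was at 19.2 CPM in YOUNG 3 and 18.5 CPM in OLD 2.

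CON-OLD-iBP against OLD asked what iBP changes in old osteoblasts. Cell cycle genes lay lower in CON-OLD-iBP, with 39 of 40 negative, a median of -1.42 and 30 lower adjusted over the list alone (camera adjusted p = 4.52e-18; adjusted p = 0.735 with an estimated correlation). The proliferation marker Mki67 stood at 32.3 ± 7.16 against 131 ± 42.2 CPM (adjusted p = 0.084), and the centromere histone gene Cenpa at 5.84 ± 0.976 against 23.3 ± 7.95 CPM (adjusted p = 0.0538). Ccne1, cyclin E1, stood at 13.1 ± 3.73 against 31.4 ± 3.63 CPM. Over all genes 4 passed. Dok5, an adaptor of receptor tyrosine kinases, rose from 10.9 ± 0.523 to 58.5 ± 13.7 CPM (n = 3; 2.42, adjusted p = 0.0459). The O-GlcNAcase gene Oga rose from 74.7 ± 2.52 to 169 ± 17.5 CPM (1.18, adjusted p = 0.0214). The cyclin-dependent kinase inhibitor gene Cdkn2d fell from 22.8 ± 6.31 to 6.59 ± 1.15 CPM (-1.79, adjusted p = 0.0459). YOUNG 3, which had no iBP, departed from YOUNG 1 and 2 in the same directions. In YOUNG 1, 2 and 3 Dok5 was at 15, 11.9 and 38.1 CPM, Oga at 82.5, 95.5 and 126 and Cdkn2d at 26.5, 22.4 and 12.1. Of the Wnt target genes 4 were higher and 1 lower adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0883). Axin2 stood at 11.9 ± 4.39 against 2.86 ± 0.422 CPM (2.06, adjusted p = 0.0833) and Tcf7 at 14.2 ± 0.91 against 4.67 ± 1.77 CPM (1.60, adjusted p = 0.0538). Tnfrsf11b, the decoy receptor osteoprotegerin, stood at 491 ± 421 against 22.9 ± 7.29 CPM. Within set 3, 19 of the 27 targets were positive (camera adjusted p = 0.00211; adjusted p = 0.724 with an estimated correlation). Lef1 stood at 1.53 ± 0.373 CPM in CON-OLD-iBP (adjusted p = 0.0867), Bglap at 35.8 ± 7.55 CPM and Cdkn2a at 141 ± 52.9 CPM.

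All 26 macrophage markers were negative in CON-OLD-iBP against OLD (median -3.57, 24 lower adjusted over the list alone). The camera adjusted p was 5.53e-17, and adjusted p = 0.735 with an estimated correlation. The receptor Csf1r stood at 41.5 ± 12.6 against 581 ± 428 CPM. Macrophage transcripts took 0.0567% to 0.114% of CON-OLD-iBP, beside 1.24%, 0.161% and 1.23% of OLD 1, 2 and 3. Of 15 osteoclast markers 13 were negative (camera adjusted p = 0.000271; adjusted p = 0.735 with an estimated correlation). Interferon response genes (25 of 33 negative) and oxidative phosphorylation genes (31 of 40 negative) had camera adjusted p of 0.0254 and 0.0126, and of 0.908 and 0.889 with an estimated correlation. Hox genes (28 of 35 positive) and chondrocyte markers (17 of 18 positive) had camera adjusted p of 0.0254 each, and of 0.735 and 0.889 with an estimated correlation. Within set 3, with OLD 2 as the only OLD library, 142 genes passed (51 higher, 91 lower). With a term for library set edgeR called 0 genes, with 1655 at an unadjusted p under 0.05. Within set 3, 39 of 40 cell cycle genes were negative with 11 lower over all genes (camera adjusted p = 5.98e-34; adjusted p = 0.28 with an estimated correlation). Without OLD 1, OLD 3, CON-OLD-iBP 1 or CON-OLD-iBP 3 edgeR called 0 genes, and the count was 1346 without OLD 2 and 118 without CON-OLD-iBP 2. At an unadjusted p under 0.05 there were 3869 genes, with 2056 by DESeq2 and 6663 by limma-voom. With median-ratio size factors 2 genes rose and 1 fell, and with library totals 4 rose and 1 fell.

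**Figure D3:**
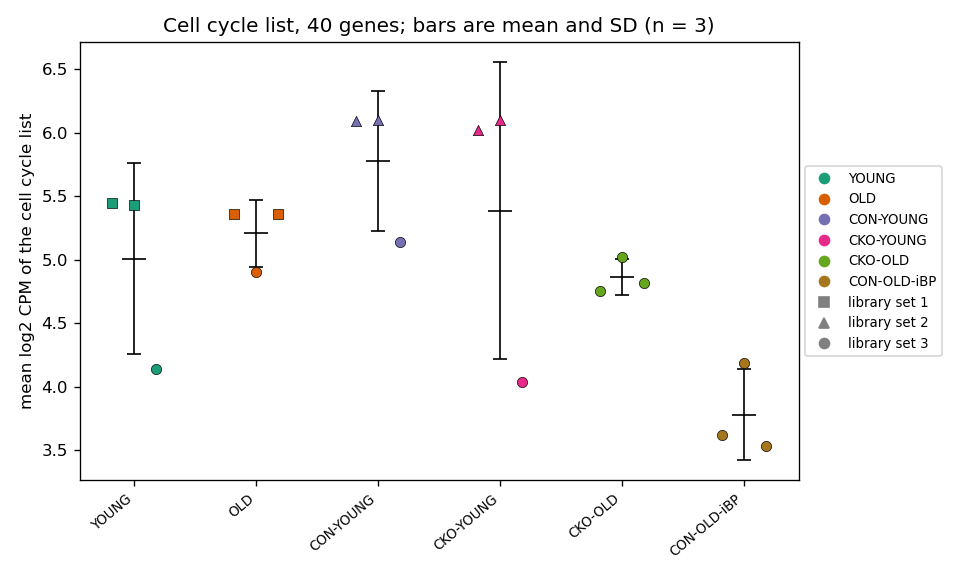
Mean log2 CPM of the 40 cell cycle genes in each of the 18 libraries by group; points are libraries, marker shape gives the library set, and bars give the mean and SD of the 3 libraries of a group. The CON-OLD-iBP libraries lie at 3.62, 4.19 and 3.53, below all 3 CKO-OLD libraries (4.75, 5.02 and 4.82).

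CON-OLD-iBP and CKO-OLD, both old and wholly within set 3, differed at 213 genes (119 higher and 94 lower in CON-OLD-iBP). Crct1, an epidermal gene, rose from 0.846 ± 0.626 to 169 ± 71.8 CPM (n = 3; 7.64, adjusted p = 0.0459). Mustn1, a gene of muscle and skeletal growth, rose from 15 ± 3.25 to 328 ± 146 CPM (4.45, adjusted p = 0.0242), and Esm1, a secreted proteoglycan, from 0.129 ± 0.123 to 6.71 ± 1.14 CPM. YOUNG 3, which had no iBP, also held Crct1 at 60.3 and Mustn1 at 104 CPM. YOUNG 1 and 2 held Crct1 at 3.12 and 2.61 CPM and Mustn1 at 9.9 and 9.35 CPM. Esm1 was at 8.38, 1.71 and 9.42 CPM in YOUNG 1, 2 and 3. Of the 21 genes higher in CKO-YOUNG 19 were negative, 9 of them called, and Bdh1 and Tchh were positive. Tmem132e fell from 8.95 ± 4.92 to 0.0471 ± 0.0817 CPM (-7.53, adjusted p = 0.0264), Grid1 from 13.6 ± 6.63 to 0.109 ± 0.0945 CPM and Lhx2 from 5.45 ± 0.767 to 0.154 ± 0.134 CPM (-5.12, adjusted p = 0.0275). Grid1 and Lhx2, not among the 21, had risen in the contrast over both ages, which shares the CKO-OLD libraries. Epop, an accessory factor of PRC2, fell from 26.2 ± 4.74 to 5.05 ± 0.505 CPM (-2.38, adjusted p = 0.0148). Aebp2, another PRC2 subunit, rose from 95.6 ± 4.1 to 180 ± 33.7 CPM (0.91, adjusted p = 0.0472). The Hedgehog target Gli1 fell from 3.73 ± 0.409 to 0.166 ± 0.227 CPM and the fibroblast growth factor receptor Fgfr2 from 92 ± 31.8 to 27 ± 8.9 CPM. The heat shock genes Hspa1a (112 ± 26.5 to 30.4 ± 9.59 CPM) and Hspa1b (191 ± 62.6 to 36.5 ± 15.6 CPM) fell. Chac1, a target of amino acid stress, rose from 16.6 ± 3.5 to 48 ± 10.2 CPM. Of 34 osteoblast genes the parathyroid hormone receptor Pth1r fell (157 ± 30.1 to 28.5 ± 12.2 CPM, adjusted p = 0.0282), 5 were lower adjusted over the list alone and 26 were negative (camera adjusted p = 0.00813). All 40 cell cycle genes (median -1.09, camera adjusted p = 5.61e-11) and all 26 macrophage markers (2.16e-06) were negative. So were 31 of 33 interferon response genes (camera adjusted p = 0.00453), 21 of 26 immediate early genes (0.000707) and 39 of 57 developmental transcription factors (0.0308). Each of these 6 lists had adjusted p = 0.956 with an estimated correlation. With the spread estimated within sets 3100 genes passed (1454 higher, 1646 lower), all of the 213 among them, and 30 cell cycle genes fell (camera adjusted p = 9.25e-22; adjusted p = 0.513 with an estimated correlation). The count was 4, 2, 5, 19 and 4 without CKO-OLD 1, CKO-OLD 2, CKO-OLD 3, CON-OLD-iBP 1 or CON-OLD-iBP 3, and 512 without CON-OLD-iBP 2. Scaling by library totals, which moved the median of all genes by -0.103, gave 93 higher and 145 lower.

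CKO-OLD against CKO-YOUNG compared ages within the knockout and called 116 genes, 56 higher and 60 lower in CKO-OLD. Bglap rose from 0.153 ± 0.153 to 58.8 ± 21.7 CPM (n = 3; 8.53, adjusted p = 0.0389). Spp1, which encodes the matrix protein osteopontin, rose from 1900 ± 434 to 11300 ± 835 CPM (2.57, adjusted p = 0.0253), while Smpd3 fell from 107 ± 32 to 17.7 ± 3.14 CPM (-2.60, adjusted p = 0.0392). Plxdc1 (0.168 ± 0.099 to 10.4 ± 8.49 CPM) and Vat1l (0.248 ± 0.0896 to 8.87 ± 4.27 CPM) rose. Smoc1, a matrix calcium-binding protein, fell from 114 ± 86.4 to 1.71 ± 0.926 CPM. The amino acid transporter Slc38a4 (10.4 ± 3.72 to 0.234 ± 0.207 CPM) and the adenosine receptor Adora2a (19.8 ± 14 to 1.05 ± 0.251 CPM) fell too. Of 25 heat shock and unfolded protein response genes 3 fell, and the list did not pass (camera adjusted p = 0.0726). Trib3 fell from 51.3 ± 17.2 to 9.83 ± 2.66 CPM (adjusted p = 0.0253), Chac1 from 42.4 ± 12.7 to 16.6 ± 3.5 CPM and asparagine synthetase, Asns, from 203 ± 81 to 73.9 ± 4.42 CPM. Of 26 immediate early genes 22 were positive and 18 were higher adjusted over the list alone (camera adjusted p = 9.93e-11; adjusted p = 0.187 with an estimated correlation). The nuclear receptors Nr4a1 (17 ± 4.11 to 263 ± 35 CPM, adjusted p = 0.0253) and Nr4a2 (6.05 ± 1.57 to 44.3 ± 6.59 CPM) were its members that rose over all genes. The cytokine Il6 rose from 0.441 ± 0.134 to 7.93 ± 0.372 CPM. Its list of 42 senescence-associated secreted factors had 8 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.000264; adjusted p = 0.187 with an estimated correlation). Macrophage markers (24 of 26 positive, 9.93e-11), osteocyte markers (11 of 12 positive, 0.00689) and chondrocyte markers (17 of 18 positive, 0.00122) were higher as lists. Fibrillar collagen genes (25 of 34 negative, 8.96e-05) and cell cycle genes (39 of 40 negative, 0.000463) were lower. With an estimated correlation the adjusted p of these 5 lists was 0.492, 0.187, 0.507, 0.492 and 0.623. The mean log2 CPM of the cell cycle list was 6.02 and 6.1 in CKO-YOUNG 1 and 2, but 4.04 in CKO-YOUNG 3. The last lay below CKO-OLD 1, 2 and 3 (4.75, 5.02 and 4.82), so the lower list rests on CKO-YOUNG 1 and 2. The Wnt receptor Ryk fell from 284 ± 7.26 to 180 ± 4.43 CPM (adjusted p = 0.0392).

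The difference of the age contrast between CKO and wild type called 0 genes by edgeR, with 1993 at an unadjusted p under 0.05, 274 by DESeq2 and 5664 by limma-voom, and 65 by edgeR without CKO-YOUNG 3. Of the osteoblast genes 25 of 34 were positive in that difference and 6 were higher adjusted over the list alone (camera adjusted p = 1.03e-05; adjusted p = 0.117 with an estimated correlation). It was 1 of 22 lists that passed. Markers of other cell types moved with it: macrophage (25 of 26 positive), chondrocyte (17 of 18) and Schwann and neural markers (11 of 12) had camera adjusted p of 9.07e-14, 2.39e-06 and 1.33e-06, and of 0.337, 0.337 and 0.0954 with an estimated correlation. Immediate early genes were higher (24 of 26 positive, camera adjusted p = 1.48e-12) and cell cycle genes lower (39 of 40 negative, 4.09e-06), with adjusted p of 0.117 and 0.542 with an estimated correlation. Within CKO the cell cycle direction rests on CKO-YOUNG 1 and 2, since CKO-YOUNG 3 lay below every CKO-OLD library. For CKO-OLD against CKO-YOUNG within set 3, where CKO-YOUNG 3 is the only young library, 892 genes passed (448 higher, 444 lower). With a term for library set 6 passed (5 higher, 1 lower), and Bglap, higher by 6.34, did not (adjusted p = 0.101), while within set 3 it was higher by 7.57 (adjusted p = 0.00294). Under that term Smoc1, Slc38a4 and Adora2a were lower by -3.04, -3.93 and -1.64, none of them called. Adora2a stood at 26.2, 29.6 and 3.78 CPM in CKO-YOUNG 1, 2 and 3. Leaving out any CKO-OLD library, CKO-YOUNG 1 or CKO-YOUNG 2 left 0 calls by edgeR, as did leaving out set 1, and leaving out CKO-YOUNG 3 gave 2655. At an unadjusted p under 0.05 there were 4065 genes, with 1999 by DESeq2 and 8538 by limma-voom. Scaling by library totals, which moved the median of all genes by 0.119, gave 54 higher and 36 lower.

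CON-YOUNG against YOUNG set side by side 2 young groups without the knockout, of different mouse lines. It called 919 genes, 285 higher and 634 lower in CON-YOUNG. Of 26 macrophage markers 25 fell, with a median of -5.15 (camera adjusted p = 1.57e-29; adjusted p = 0.362 with an estimated correlation). Cd68 fell from 376 ± 262 to 9.7 ± 6.17 CPM (n = 3; adjusted p = 0.0141), Csf1r from 752 ± 476 to 19.6 ± 12.4 CPM and Laptm5 from 491 ± 269 to 14.2 ± 6.63 CPM. Macrophage transcripts took 1.72%, 1.11% and 0.383% of YOUNG 1, 2 and 3 and 0.0218%, 0.0223% and 0.0535% of CON-YOUNG 1, 2 and 3. Senescence-associated secreted factors had 9 of 42 lower and 16 lower adjusted over the list alone (camera adjusted p = 2.62e-06; adjusted p = 0.213 with an estimated correlation). Among them the cytokines Il6 (5.21 ± 1.51 to 0.626 ± 0.41 CPM), Tnf (124 ± 103 to 0.797 ± 0.959 CPM) and Ccl2 (220 ± 177 to 21 ± 16.4 CPM) fell. Il1b was at 31 ± 25.8 CPM in YOUNG and at 0 in CON-YOUNG, at least 1760-fold lower. Il1b was at 51.2, 40 and 1.87 CPM and Tnf at 210, 150 and 10.4 CPM in YOUNG 1, 2 and 3. The chemokine Ccl3 (90.5 ± 87 to 0.49 ± 0.389 CPM) and the granin gene Scg2 (13.3 ± 22.1 to 0.0306 ± 0.0531 CPM) fell too. Scg2 was at 38.8, 0.174 and 0.83 CPM in YOUNG 1, 2 and 3 and called in 6 of 14 alternatives. Within set 3, CON-YOUNG 3 against YOUNG 3, Il1b was at 0 against 1.87 CPM, Tnf at 1.88 against 10.4, Ccl2 at 39.9 against 55 and Ccl3 at 0.933 against 4.56. Il6 was at 1.04 against 5.54 CPM there, Cd68 at 16.8 against 101, Csf1r at 34 against 224 and Laptm5 at 21.9 against 195. Neither these nor the genes before them were called there, with 1 library a side, so the lost calls do not show that the differences went away. Without YOUNG 1 the log2 fold changes of Tnf, Ccl2 and Ccl3 were -6.65, -2.59 and -6.56, against -7.28, -3.39 and -7.52 with it. Of 26 immediate early genes 5 fell and 14 were lower adjusted over the list alone (camera adjusted p = 1.13e-06; adjusted p = 0.362 with an estimated correlation). Atf3 fell from 186 ± 146 to 15.3 ± 11.8 CPM, Egr2 from 46.7 ± 41.8 to 7.07 ± 3.44 CPM and Dusp1 from 900 ± 31.6 to 280 ± 247 CPM. Within set 3 the log2 fold change was -0.02 for Atf3, -0.68 for Dusp1 and 0.71 for Egr2, none of them called. Adora2a rose from 0.616 ± 0.353 to 11.9 ± 9.01 CPM, the transcription factor Ebf3 from 5.1 ± 1.46 to 55.7 ± 44.3 CPM and Serpina3g from 1.09 ± 1.04 to 12.5 ± 10.5 CPM. Within set 3 these 3 differed by 0.50, 2.01 and 3.68, none of them called. Cell cycle genes (37 of 40 positive, camera adjusted p = 2.62e-06), Wnt receptors (3 higher, 6.64e-05) and Hox genes (2 higher, 0.000392) were higher as lists. Their adjusted p was 0.582, 0.451 and 0.362 with an estimated correlation. Bglap stood at 3.35 ± 5.66 against 61.1 ± 14.4 CPM (-4.19, adjusted p = 0.076). Within set 3, with 1 library a group, 22 genes passed, 4 of them among the 919, and without set 1 there were 8. With a term for library set edgeR called 0, with 1558 at an unadjusted p under 0.05. With the replicate number as a block, fitted on these 2 groups alone with few residual degrees of freedom, 0 genes passed by edgeR. The 0 therefore does not show that pairing removes the difference. Without a block, the edgeR fit over all 18 libraries gave 3816 genes at an unadjusted p under 0.05. DESeq2 called 2063 and limma-voom 7537, also without a block. Under the block 22 lists passed camera in place of 13. Without YOUNG 1, CON-YOUNG 1 or CON-YOUNG 2 there were 0 calls, without YOUNG 2 there were 304 and without CON-YOUNG 3 there were 2924.

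Of the fixed lists, 9 passed camera in none of the 10 comparisons: matrix proteases, BMP and TGF-beta signalling, Notch signalling, Cdkn inhibitors and p53 targets, germline genes, and the markers of endothelial cells, skeletal muscle, erythroid cells and B lymphocytes.

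The fold changes of CKO-OLD against OLD and of CKO-YOUNG against CON-YOUNG, which share no library, correlated across genes at r = 0.104, against -0.007 in 20 simulations of unchanged groups (covariance 0.17 against -0.007). They shared 1 call, Tcfl5, with 0.00127 expected of independent lists. The 21 genes higher in CKO-YOUNG were selected on fold changes of the young libraries, which the comparisons between old groups do not contain. The spread behind the selection was estimated over all libraries, the old ones included, so the selection was not wholly separate. In CKO-OLD against OLD, 19 of them were positive and 17 had an unadjusted p under 0.05 (median log2 fold change 2.17, limma fry p adjusted over 4 comparisons, adjusted p = 3.72e-08). In CON-OLD-iBP against CKO-OLD, 19 were negative and 9 of these passed (median -1.93, fry adjusted p = 3.72e-08). This contrast uses the same CKO-OLD libraries as the one before, so it is not an independent result. In CON-OLD-iBP against OLD, 11 were positive and 10 negative (fry adjusted p = 0.699). The contrasts of CKO-OLD and CON-OLD-iBP against the same OLD libraries correlated at r = 0.523, against 0.491 in the simulations, with a covariance of 0.994 against 0.447. OLD against YOUNG correlated with them at r = -0.445 and -0.453 (simulated -0.497 and -0.492), with covariances of -0.552 against -0.449 and -0.716 against -0.445. OLD has 3 libraries and could not be split into parts of 2, so part of these differences may come from the shared OLD libraries. The simulations also held no library sets. CKO-OLD and CON-OLD-iBP lie wholly in set 3 and OLD 1 and 3 in set 1. That difference enters both contrasts alike and may raise their covariance, so the excess does not show a shared response. OLD against YOUNG and CKO-OLD against CKO-YOUNG, with no shared library, correlated at r = 0.008 (simulated -0.002). Genes are not independent replicates in these correlations.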

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

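The tests on sex of the cells, on library set for the 21 genes and for the cell cycle list, and on one outlying library, and all counts of other splits, were chosen only after the result was seen.

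The sets of libraries bear on every comparison except CON-OLD-iBP against CKO-OLD, which lies wholly in set 3. In CKO-YOUNG against CON-YOUNG and in OLD against YOUNG both groups hold the same sets in the same numbers. Library set, as placed by Malat1, adds to the spread there and does not part the groups. Between CON-YOUNG 3 and CON-YOUNG 1 and 2, all with Y-linked transcripts and little Xist, 2882 genes passed the edgeR threshold, which argues against sex of the cells as the whole cause for that library. Handling shared by all Malat1-low libraries would make the high-minus-low fold changes alike in both series, and these correlated across genes at r = 0.133, under the bound of 0.2 set beforehand. CKO-YOUNG 3, which stood apart from set 3, enters the fold changes of the knockout series. Sex and macrophage share enter those of YOUNG and OLD. Both may lower r, so shared handling as part of the cause is not excluded. RNA from macrophages stays open for YOUNG and OLD: 35 genes were called and at least 4-fold lower in the Malat1-low libraries in both groups, between the 10 that dilution would allow and the 50 that would speak against it. Sex, macrophage share and Malat1 share move together in set 1, and no label gives a date or batch, so what made the sets cannot be told apart further here.

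The 21 genes higher in CKO-YOUNG form the next pattern. Both young groups hold 2 libraries of set 2 and 1 of set 3, so library set by that placement could not part them. The count that follows was therefore not needed for that question and adds no support. With all 6 libraries in one set, 19 of the 21 had negative fold changes in CON-OLD-iBP against CKO-OLD, called or not. The prediction was 15 or fewer if library set were the cause. The count shows only that the direction recurred between old groups. Genes carried along beside the targeted locus are argued against, since 0 of the 21 lie among the 100 tested genes nearest to Kdm2b in GRCm38. A response to the Kdm2b deletion may explain them, as a hypothesis from one series, with genes chosen on the young libraries and followed in the old ones. No young library had iBP, so it cannot account for the young difference; culture state stays open and untested.

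The cell cycle list is the last. All 3 CON-OLD-iBP libraries lay below every CKO-OLD library in the list's mean log2 CPM, so one outlying library is not the cause. All 6 libraries lie in set 3 from the start, so the 40 members lower there repeat the result and test nothing about library set. YOUNG 3 and CKO-YOUNG 3, which had no iBP, lay as low (4.14 and 4.04) as CON-OLD-iBP 2 (4.19). CON-OLD-iBP 1 and 3 (3.62 and 3.53) lay below every library without iBP. A difference in growth state of the cultures stays open beside an effect of iBP, as neither was tested.

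Other splits of the same 6 libraries into 3 against 3 make 10 splits, too few for a share under 0.05. The counts of genes, with the highest of the other splits, were 21 and 5 in CKO-YOUNG against CON-YOUNG, 1 and 4 in CKO-OLD against OLD (2 of the 10 splits had as many), 4 and 0 in CON-OLD-iBP against OLD, 213 and 0 in CON-OLD-iBP against CKO-OLD, 116 and 1 in CKO-OLD against CKO-YOUNG, 919 and 23 in CON-YOUNG against YOUNG, and 0 and 3 in OLD against YOUNG (10 of 10 splits with as many); in each of the other 5 comparisons 1 split, the real one, had as many. The split with 4 genes set CKO-OLD 1 and 3 and OLD 2 against CKO-OLD 2 and OLD 1 and 3. It follows Malat1 in part and separates the libraries by macrophage share, at 0.158% to 0.2525% against 0.677% to 1.24%. The split with 23 set CON-YOUNG 1 and 2 and YOUNG 3 against CON-YOUNG 3 and YOUNG 1 and 2, with 2 Malat1-low libraries on each side. For CKO over both ages, 3 of 100 drawn splits gave 88 genes or more. Of the 41 that part all 3 same-numbered young pairs only the real one did, with 1 gene in the highest of the others. A share of 3 in 100 lies under 0.05 if the libraries of an age can be exchanged freely. OLD 1 and 3 are in set 1 and all of CKO-OLD in set 3, so they may not be exchangeable. Splits that keep the library sets were not drawn, so chance is not excluded. The highest of all the others gave 167 (the next 106), with OLD 2, CKO-OLD 1 and 3, CON-YOUNG 1 and CKO-YOUNG 1 and 2 on one side. This points to structure in the samples that follows the library sets in part, and the macrophage share within each age. That share was 0.158% to 0.2525% on this side against 0.677% to 1.24% in the old libraries. In the young ones it was 0.016% to 0.0218% against 0.0223% to 0.113%. With a term for library set the real split gave 129. For the difference of the knockout contrast between ages, and of the age contrast between CKO and wild type, the real count was 0, all 100 of 100 splits gave as many, and the highest gave 167 and 9. These draws were first made with fewer splits and then extended to 100 once the first counts were known.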

How the results depend on the processing

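The fits with a term for library set, within library sets and without set 1, and the contrast of CKO over both ages, were chosen only after the data were seen. Named genes were followed whether called or not. Of 1559 values under the alternatives set before the data were seen 1210 kept direction and side of the threshold, 311 lost and 38 gained the call and 0 reversed, and of 676 under the added ones 529 did, with 130 lost, 15 gained and 2 reversed. These counts include genes that were uncalled throughout. Of 64 called results, 5 were called in every alternative other than those on library set and 54 in more than 0.5 of them. A further 67 values changed sign with neither value called. Of 1284 values of lists 1014 kept their side, 234 lost and 36 gained it. The reversed values are those of Egr2, CON-YOUNG against YOUNG, with a log2 fold change of 0.09 without set 1 and 0.71 within set 3, not called in either. Adjusted p of named genes ranged widely over the alternatives: 1.1e-14 to 0.296 for Tcfl5 in CKO-OLD against OLD (called in 12 of 15), 1.18e-18 to 0.27 for Mafa in CKO-YOUNG (13 of 15), 1.14e-06 to 0.183 for Bglap in CKO-OLD against CKO-YOUNG (10 of 15), 0.000127 to 0.335 for Egr2 in CON-YOUNG against YOUNG (9 of 15) and 4.36e-11 to 0.22 for Oga in CON-OLD-iBP against OLD (10 of 15). The causes of the changes below were not tested, except where the construction of an alternative shows it. Counts follow the order OLD against YOUNG, CKO-YOUNG against CON-YOUNG, CKO-OLD against OLD, CON-OLD-iBP against OLD, CON-OLD-iBP against CKO-OLD, CKO-OLD against CKO-YOUNG, CON-YOUNG against YOUNG, the difference of the knockout contrast between ages, the difference of the age contrast between CKO and wild type, and CKO over both ages, for which the planned edgeR test gave 0, 21, 1, 4, 213, 116, 919, 0, 0 and 88.

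DESeq2 gave 41, 230, 181, 2056, 1421, 1999, 2063, 48, 274 and 412 genes, and limma-voom with quality weights 1125, 499, 6820, 6663, 2873, 8538, 7537, 2742, 5664 and 3940. The weights, by construction, count the libraries close to the rest of their group for more: 4.69 and 4.94 for OLD 1 and 3 against 0.271 for OLD 2, and 0.237, 0.167 and 0.176 for YOUNG 3, CON-YOUNG 3 and CKO-YOUNG 3. Median-ratio size factors, removal of the 20 genes of highest counts and a fold threshold of log2 1 gave no total, higher and lower together, that differed by over 1.5 times, and neither did library totals. By direction some did. Library totals gave 145 lower in place of 94 in CON-OLD-iBP against CKO-OLD and 36 lower in place of 60 in CKO-OLD against CKO-YOUNG. The fold threshold gave 75 higher in place of 119 in CON-OLD-iBP against CKO-OLD and 154 higher in place of 285 in CON-YOUNG against YOUNG. In CON-OLD-iBP against OLD the 2 lower became 1 with median-ratio factors, library totals or without the 20 genes, and the 2 higher became 4 with library totals. In CKO over both ages the 2 lower became 1 with library totals and with the fold threshold. Without a filter, CKO-OLD against OLD gave 2 genes and CON-OLD-iBP against CKO-OLD 125, and the filter of 5 CPM in 3 libraries gave 518 in CON-OLD-iBP against OLD and 210 in CKO-OLD against CKO-YOUNG.

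Fits on the groups compared alone, with 4 residual degrees of freedom for a pair of groups, gave 4, 4, 30, 679, 736 and 1 genes from CKO-YOUNG against CON-YOUNG to CON-YOUNG against YOUNG, and 61 for the difference of the age contrast. With the replicate number as a block these were 0, 0, 2, 649, 230, 0 and 22, with 50 for CKO over both ages. The block leaves fewer residual degrees of freedom, so its lower counts do not by themselves show that pairing removes differences. All same-numbered pairs lay over a correlation of 0.1 only in CKO-YOUNG against CON-YOUNG and CON-YOUNG against YOUNG, where both replicates 3 are in set 3. Elsewhere at least 1 such pair lay under 0.1. Under the block, camera passed 11 lists in CON-OLD-iBP against OLD and 22 in CON-YOUNG against YOUNG. With a term for library set the counts were 93, 4, 0, 2035, 6 and 0 from CKO-YOUNG against CON-YOUNG to CON-YOUNG against YOUNG and 1 for the difference of the age contrast. Within set 1 OLD against YOUNG gave 63, within set 2 CKO-YOUNG against CON-YOUNG 76, and within set 3 the first 7 comparisons gave 9, 1113, 9, 142, 3100, 892 and 22. In set 3 only CKO-OLD and CON-OLD-iBP have more than 1 library, so in the other 6 comparisons other groups supply the spread of at least 1 side. Without set 1, CKO-YOUNG against CON-YOUNG gave 8, CKO-OLD against OLD 0, CON-OLD-iBP against OLD 0, CKO-OLD against CKO-YOUNG 0, CON-YOUNG against YOUNG 8 and CKO over both ages 1; this leaves 1 library each in YOUNG and OLD, assumed to vary like the other groups, and removes libraries from the shared estimate of the spread.

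Leaving out each library in turn gave 0 to 2, 2 to 23, 0 to 48, 0 to 1346, 2 to 512, 0 to 2655, 0 to 2924, 0 to 0, 0 to 65 and 24 to 119 genes. The highest counts came without YOUNG 3, CON-YOUNG 3, OLD 2, OLD 2, CON-OLD-iBP 2, CKO-YOUNG 3 and CON-YOUNG 3 in the first 7 comparisons, 6 of them the only set 3 library of its group.

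Lists past the threshold of camera numbered 16, 6, 19, 7, 6, 14, 13, 12, 22 and 12 with the preset correlation, 1, 0, 1, 0, 0, 0, 0, 0, 0 and 1 with an estimated one, and 0, 0, 2, 0, 0, 8, 10, 0, 6 and 2 by fry. A larger correlation between genes widens the error of a list by construction.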

Other observations

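The test of a mixture of cells in CKO-YOUNG 3 was chosen only after the values were seen, and the genes in this part were picked in the same way.

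Interferon response genes differed more within CKO-YOUNG than between groups. Isg15, a ubiquitin-like protein induced by interferon, stood at 7.3, 3.46 and 283 CPM in CKO-YOUNG 1, 2 and 3 and at 26.8, 20.2 and 4.59 CPM in CON-YOUNG 1, 2 and 3, and Ifit1 at 3.5, 1.78 and 135 against 17.1, 8.95 and 7.28 CPM. Over all 33 tested members the mean log2 CPM was 2.52, 2.04 and 5.52 in CKO-YOUNG and 3.86, 3.44 and 2.58 in CON-YOUNG. Within set 2, which leaves out both replicates 3, all 33 were lower in CKO-YOUNG (median -1.68, 25 lower adjusted over the list alone; camera adjusted p = 2.94e-38; adjusted p = 0.147 with an estimated correlation), and Irf7 fell from 25.4 ± 5.94 to 5.87 ± 2.21 CPM (n = 2; adjusted p = 0.0377), Usp18 from 12.9 ± 2.69 to 2.08 ± 0.376 CPM and Stat2 from 42.9 ± 5.5 to 19 ± 5.38 CPM. In the pooled comparison 29 of the 33 were positive and the list did not pass (camera adjusted p = 0.494). The imprinted genes Igf2 and H19 were also highest in CKO-YOUNG 3, at 1370 and 607 CPM; Igf2 stood at 99.6 and 97.1 CPM in CKO-YOUNG 1 and 2 and at 50.7, 115 and 123 CPM in CKO-OLD, while H19 stood at 7.68 and 5.55 CPM in CKO-YOUNG 1 and 2.

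Bcor, the PRC1.1 subunit that joins Kdm2b and Pcgf1 in that complex, stood at 194, 239 and 101 CPM in CKO-YOUNG against 82.1, 86.6 and 25.9 CPM in CON-YOUNG (log2 fold change 1.46, edgeR adjusted p = 0.373), at 69.2, 120 and 97.8 CPM in CKO-OLD against 32.7, 37.2 and 30.6 CPM in OLD (1.51, adjusted p = 0.367), and at 31.3, 43.2 and 18.6 CPM in CON-OLD-iBP. Chondrocyte markers were high in single libraries of several groups: the mean log2 CPM of 18 genes was 6.01 in YOUNG 3, 5.93 in CON-OLD-iBP 1 and 5.15 in CKO-OLD 3, and 0.75 to 3.29 in the other 15 libraries. Klra4, a receptor gene of natural killer cells, was read at 6.6 to 9.07 CPM in OLD and 6.02 to 21 CPM in CON-OLD-iBP and at 0 CPM in YOUNG, CON-YOUNG, CKO-OLD and CKO-YOUNG 1 and 2, with 1.27 CPM in CKO-YOUNG 3.

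CKO-YOUNG 3 held both Xist (372 CPM, against a mean of 439 in set 1) and Y-linked transcripts at 0.299 to 0.365 of their mean in male libraries (mean share 0.342). The male share and the female share from Xist (0.847) sum to 1.19, near the sum of 1 that a mixture of male and female cells needs, so such a mixture may account for both, as a hypothesis; it says nothing of the interferon or Igf2 values of that library, whose cause was not tested.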
